A study of Mus musculus with 8 samples.

How the data were processed

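The study measured RNA by sequencing in heart tissue of 8 male BALB/cAJcl mice, 10 weeks old, with autoimmune myocarditis. Per the labels, 4 animals were given VEGF-C C156S at 1 µg per day and 4 were given PBS, from day 7 to day 10 after immunization, and the hearts were taken in week 3. Per the labels' protocols, total RNA with a RIN above 8.0 was made into libraries with a stranded mRNA kit and sequenced on an Illumina NovaSeq instrument. The title of the series speaks of cardiac lymphatic endothelial cells, but every sample label gives heart as the tissue, so the values were read as those of whole heart tissue. The groups were taken from the treatment label of each sample. The animal numbers in the labels do not repeat between the groups, so no pairing was used, and each sample was counted as 1 animal. The 8 columns of the deposited table name the group and a number that ties to no animal; the replicate numbers used here are those column numbers.

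Per the submitters' processing notes, the tools were Trim Galore 0.6.10, STAR 2.7.10a, featureCounts, Subread 2.0.1 and DESeq2 1.38.3, with the genome build GRCm39; the annotation release, the strand setting of the counting and the settings of each tool are not given in the sources used here. The deposited table lists 56941 genes and gives values for 18835 of them, so the authors removed 38106 genes by a rule that is not given in the sources used here. The deposited expression values are on a log2 scale. Read back from the values, each is log2(x + 4), where x is a read count divided by 1 factor per library: 100% of the values in every library came out as a whole number of reads, with a tolerance of 0.01 reads. Those factors equalled median-of-ratios size factors computed from the recovered reads (ratio 1 in each library). The authors' own log2 fold change and adjusted p-value per gene are deposited in the same table; the adjusted p-value is missing for 23 genes. A log2 fold change on this scale understates the change of genes with few reads.

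Depth was taken from the recovered reads over the 18835 genes. It was 76.0, 61.7, 66.4 and 76.8 M reads in PBS replicates 1 to 4 and 65.2, 53.7, 61.6 and 62.5 M in VEGF-C replicates 1 to 4. These totals leave out the reads of the genes without values.

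The quasi-likelihood count test of edgeR, planned before the data were examined for a table of counts, was not run on these log2 values. In its place limma 3.58.1 (R 4.3.3) was used on the deposited log2 values of all 18835 genes. The model had 1 factor, the treatment, with 6 residual degrees of freedom and moderated variances with a mean-variance trend. Adjusted p-values are Benjamini-Hochberg values over all genes, two-sided, with a threshold of 0.05. Fold changes are VEGF-C against PBS, with the standard error of the model; values per group are mean ± SD of 4 animals.

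Before the data were examined, 43 gene lists with 552 entries were fixed: markers of cell types in or near an inflamed heart, inflammatory pathways, matrix, contractile and metabolic genes. Of the entries, 13 had no value and 1 was matched through a synonym. Each list with at least 3 measured members was tested with fry, a rotation test in limma that asks whether the members move on balance in one direction and does not compare the list with other genes, with Benjamini-Hochberg adjustment over the 43 lists. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Beside fry, camera, which compares a list with the other genes, was run with a preset correlation of 0.01 and with an estimated correlation. An exact two-sided permutation test of the list means was run over the 70 assignments of the libraries, whose smallest p is 0.0286.

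The genes named were chosen by a rule fixed before the data were examined. Among genes past the threshold with a CPM of at least 1 in the higher group, it took the 10 with the smallest p-value and the 3 with the largest change in each direction. It then took up to 4 members with the smallest p-value of each list that passed and up to 2 of each other list, used here only for members past the threshold. Vegfc, Flt4, Prox1, Lyve1, Pdpn, Adgre1, Cd68, Nppb, Myh7, Col1a1, Myh6 and Ddx3y were fixed by name. Predicted genes and V, D and J segments were not named, and a few genes that met the rule are not reported. Xist, also fixed by name, has no values in the deposited table. Genes named outside this rule are said to be chosen after their values were seen. Genes of families with near-identical members (hemoglobins, immunoglobulins, histocompatibility genes), pseudogenes and genes that overlap or lie antisense to another gene are uncertain, since the counting settings are not given in the sources used here.

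Gene classes came from the GENCODE M21 annotation by gene ID, which matched 18472 genes (98.1%). That annotation is of another build than the deposited values, so no coordinates are given. The limma test was tested on simulated data made from the means, library sizes and spread of the real genes for VEGF-C against PBS: among 18835 genes with 200 changed genes, it recovered 24% of those changed by 0.5 on the log2 scale, 58% of those changed by 1, 90% of those changed by 2 and 94% of those changed by 3, with 7 false calls.

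Alternatives fixed before the data were examined were upper-quartile factors, library totals, a stricter filter (CPM of at least 1 in at least 4 libraries), leaving out mitochondrially encoded genes, limma-voom on the recovered reads with and without sample quality weights, other thresholds, a pseudocount of 2, leaving out each library in turn, and the other list tests. Added after the data were seen were TMM factors, a robust variance fit, a pseudocount of 1, protein-coding genes only, the first residual component as a covariate, thinning of the reads to 1 normalized depth, a comparison of each list median with 10000 random protein-coding lists matched on mean value (which takes genes as independent), and the authors' deposited adjusted p-value. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.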

Results

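RNA was sequenced from the hearts of 8 male mice with experimental autoimmune myocarditis, an inflammation of the heart muscle set off by immunization against cardiac myosin. Of these animals, 4 had received VEGF-C C156S, a form of the lymphatic growth factor VEGF-C that acts through the receptor VEGFR-3 (the product of Flt4), and 4 had received PBS. The comparison asks how heart tissue of treated animals differed from that of controls in week 3. Read totals were between 61.7 and 76.8 M in the PBS group and between 53.7 and 65.2 M in the VEGF-C group. Ddx3y, a gene of the Y chromosome, was read in both groups, at 11.16 ± 0.17 in PBS and 11.27 ± 0.23 in VEGF-C (log2 values, SD, n = 4).

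Several long noncoding RNAs were lower in hearts of VEGF-C-treated animals. Of 43 gene lists, 6 passed the rotation test fry: those of B and plasma cells, alternatively activated macrophages and Schwann cells as lower, and those of oxidative phosphorylation, glycolysis and the contractile apparatus as higher. All 6 had an adjusted p = 0.724 with an estimated correlation in camera, the lowest value of any list, shared with lists that did not pass fry. In each of the 6 a minority of members passed singly, at most 6 of 14. Of 18835 genes tested, 2949 (15.7%) passed an adjusted p of 0.05 in limma, 1328 higher and 1621 lower in VEGF-C. Changes of at least 2-fold were mostly decreases, with 23 genes higher and 612 lower. The 2 groups did not overlap in 4336 genes (23.0%), where chance gives 2.86%. The authors' deposited table has 4075 genes under an adjusted p of 0.05, 1927 higher and 2148 lower, and 2947 of the genes called here are among them, 0 of these with the opposite sign. The balance of directions depended on the scaling: with library totals only, 243 genes were higher and 3572 lower, and with upper-quartile factors 769 were higher and 1937 lower. Library totals moved the median of all genes by -0.19 (log2). Without VEGF-C replicate 1 the count was 1956 and without VEGF-C replicate 3 it was 1684. The number higher was 851 and 818 without PBS replicates 2 and 3, and 780, 857, 591 and 840 without VEGF-C replicates 1 to 4.

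**Figure D1:**
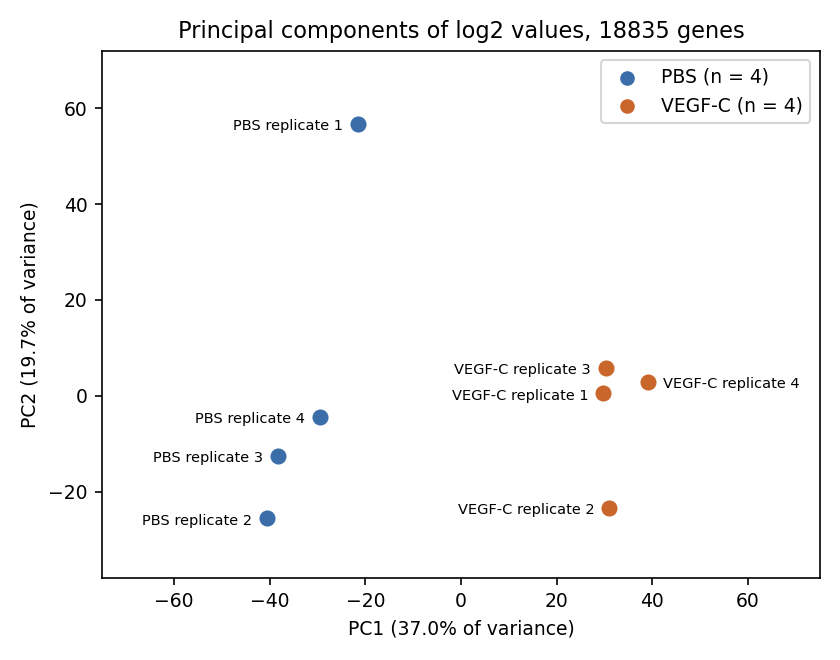
Principal components of the log2 values of 18835 genes, 1 point per library, with the share of variance on each axis. The 4 PBS libraries lie between -40.6 and -21.6 on the first component and the 4 VEGF-C libraries between 29.6 and 39.2; PBS replicate 1 lies at 56.8 on the second component.

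The first principal component held 37.0% of the variance and parted the groups. The second, with 19.7%, set PBS replicate 1 (56.8) apart from the other 7 libraries. In that library the interferon gamma response list averaged 12.59 on the log2 scale, against 10.62 to 11.49 in the other PBS libraries, and the fibroblast identity list averaged 12.94, against 13.45 to 13.64. Spearman correlations across genes were at least 0.976 within PBS, at least 0.988 within VEGF-C and at least 0.975 between the groups.

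The strongest decreases were in long noncoding RNAs. Neat1 (ENSMUSG00000092274), the scaffold of nuclear paraspeckles, fell from 71305 ± 7060 to 15480 ± 630 normalized counts (SD, n = 4), a log2 fold change of -2.20 ± 0.09 (SE) with a limma adjusted p of 2.94e-06. Firre (ENSMUSG00000085396), a nuclear RNA of the X chromosome, fell from 3935 ± 175 to 689 ± 133 normalized counts, and the imprinted RNA Meg3 (ENSMUSG00000021268) from 7189 ± 2077 to 1039 ± 117. Mirt1 had the largest decrease among the named genes, -2.82 ± 0.30, and the small nucleolar RNA host gene Snhg20 fell by 2.03. Protein-coding genes with the smallest p-values among the decreases were Msh5, a gene of meiotic recombination (-1.84), Metap1d, a mitochondrial methionine aminopeptidase (-1.65), Shfl, an interferon-induced inhibitor of frameshifting (-1.57), Arhgap4 (-1.41), Ushbp1 (-1.28), Fam193b (-1.18) and Snrnp70 (-1.15), which encodes a protein of the U1 spliceosome particle. All 4 VEGF-C libraries were below all 4 PBS libraries in each of these genes.

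Among the increases, the transcription factor Zbtb16 (ENSMUSG00000066687) rose most, from 1458 ± 334 to 6782 ± 2197 normalized counts (SD, n = 4), a log2 fold change of 2.20 ± 0.22 (limma adjusted p = 0.000389). Mypn (ENSMUSG00000020067), which encodes the sarcomere protein myopalladin, rose from 7124 ± 956 to 13841 ± 199 normalized counts. Smaller increases with little spread were those of Synpo, an actin-binding protein (0.72), Ptms (0.69), Rin3 (0.66), Wbp2 (0.63), the ubiquitin-conjugating enzyme Ube2r2 (0.63), the translation initiation factor Eif5b (0.60) and the poly(A)-binding protein Pabpc1 (0.58). Fam107a rose by 1.80 ± 0.28 and Tubb1, the beta-tubulin of platelets, by 1.86 ± 0.48; the call of Tubb1 was lost without any 1 library except PBS replicate 1 and VEGF-C replicate 4 (limma adjusted p up to 0.0717). Rps6-ps4 rose from 375 ± 31.8 to 988 ± 135 normalized counts, but it is a ribosomal protein pseudogene and its reads are hard to tell from those of its parent gene.

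**Figure D2:**
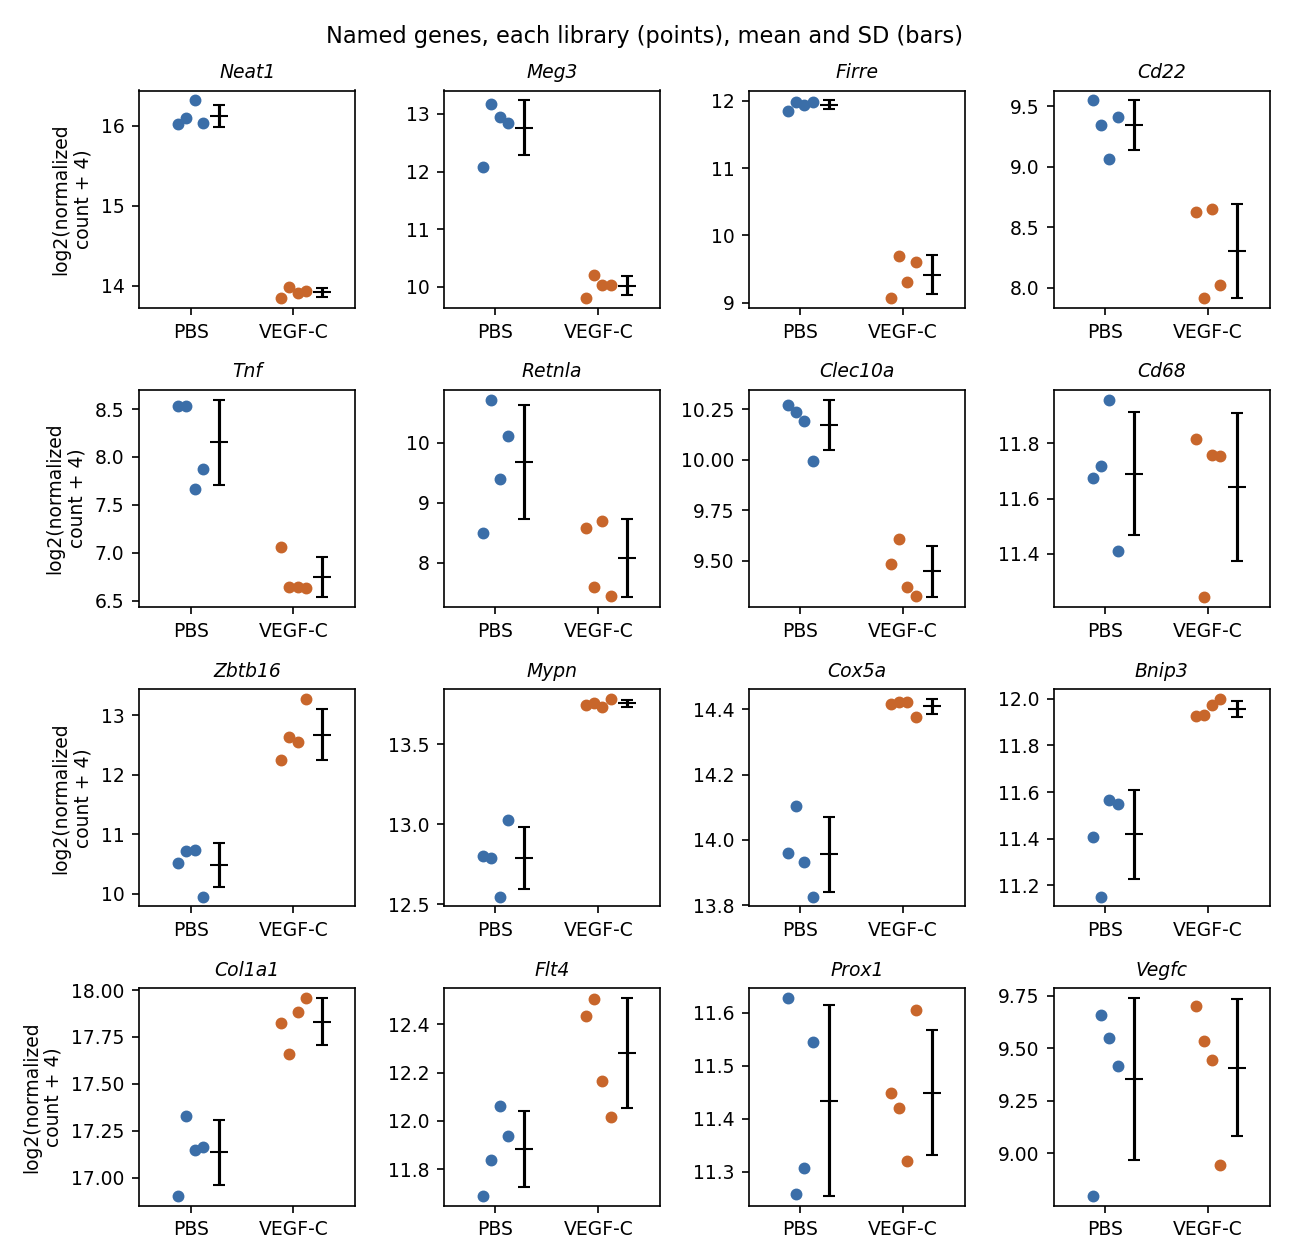
Log2(normalized count + 4) of 16 named genes in each library (points; blue PBS, orange VEGF-C), with the mean and SD of each group of 4 beside them. Neat1, Meg3, Firre, Cd22, Tnf and Clec10a are lower in all 4 VEGF-C libraries than in any PBS library, Zbtb16, Mypn, Cox5a, Bnip3 and Col1a1 are higher, and Cd68, Prox1 and Vegfc overlap.

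B cell genes were lower in VEGF-C. All 14 measured members of the B and plasma cell list had negative fold changes, with a median of -1.31, against -0.16 to 0.19 for 95% of matched coding lists; 5 passed over all genes and 9 adjusted over the list alone. The immunoglobulin delta chain gene Ighd fell by 1.91 ± 0.43, the receptor component Cd79a by 1.56 ± 0.36 and Cd22 by 1.04 ± 0.19. The list passed fry (adjusted p = 0.0469; adjusted p = 0.724 with an estimated correlation). This call was lost with TMM factors (0.0501) and upper-quartile factors (0.0594), and without any 1 library except PBS replicate 1 (fry adjusted p up to 0.130). T cell genes had a median of -0.11 (fry adjusted p = 0.617), with 0 of 16 members past the threshold. The lists of regulatory T cells and checkpoints (median -0.26), helper T cell effectors (-0.12) and cytotoxic and NK cells (-0.29) did not pass (fry adjusted p = 0.398, 0.772 and 0.414). Members that passed in them were the costimulatory receptor Tnfrsf18 (-1.02) and the transcription factor Eomes (-1.10). The direction of the helper T cell list changed with the stricter filter. Among these genes Cd79a lost its call without VEGF-C replicate 3 (limma adjusted p up to 0.0526), and Eomes without any 1 library except PBS replicate 2 and VEGF-C replicate 4 (0.0679).

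Genes of alternatively and of classically activated macrophages had negative fold changes (medians -0.60 and -0.51), and only the alternatively activated list passed fry. No test compared the 2 lists. General macrophage markers did not pass. All 12 members of the alternatively activated list had negative fold changes (median -0.60, against -0.35 to 0.13 for 95% of matched coding lists). Over all genes 2 passed, the lectin receptor Clec10a (-0.73 ± 0.10) and the secreted protein Retnla (-1.61 ± 0.45); Arg1 (-0.88 ± 0.38) and Ccl22 (-0.99 ± 0.40) did not; adjusted over the list alone it was also 2. The list passed fry (adjusted p = 0.0319; adjusted p = 0.724 with an estimated correlation), and the call was lost without any 1 library except PBS replicate 4 (fry adjusted p up to 0.112). In the classically activated list 4 of 12 members passed, all lower, among them Tnf (-1.41 ± 0.22) and Irf5 (-0.49 ± 0.11); all 12 had negative fold changes, and the list itself did not pass (fry adjusted p = 0.0870). In the pan-macrophage list 0 of 15 members passed (median -0.05, fry adjusted p = 0.617), though the median lay just below that of 95% of matched coding lists (-0.02 to 0.23, adjusted p = 0.0516 against matched lists): Adgre1 had a fold change of 0.14 ± 0.12 and Cd68 of -0.05 ± 0.14. Of the resident cardiac macrophage list, the scavenger receptor Cd163 (-0.60 ± 0.15) and Folr2 (-0.70 ± 0.21) passed and the list did not (fry adjusted p = 0.398). With limma-voom Retnla and Folr2 did not pass (adjusted p = 0.0749 and 0.0652), nor did Retnla with a robust variance fit (0.0933). Among these genes Retnla lost its call without any 1 library except PBS replicate 1 and VEGF-C replicate 3 (limma adjusted p up to 0.0933), Cd163 without PBS replicate 3 or VEGF-C replicate 1, 3 or 4 (0.0701), and Folr2 without any 1 library except PBS replicate 1 (0.115).

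Further inflammatory lists had negative medians without passing fry. In the monocyte list (median -0.39, fry adjusted p = 0.118) Ly6c2 (-0.39) passed, and in the neutrophil list (-0.63, 0.185) the protease Mmp9 (-0.91) and the receptor Csf3r (-0.77). All 16 members of the interferon gamma response list had negative fold changes (median -0.44), and 0 passed (fry adjusted p = 0.418). In the type I interferon list (-0.41, 0.147) 3 of 15 passed over all genes and 7 adjusted over the list alone, among them Mx2 (-0.67) and Oasl2 (-0.56). In the chemokine list (-0.37, 0.331) Cxcl1 was lower (-1.33 ± 0.32) and Ccl12 higher (0.74 ± 0.19). Other lists were those of MHC class II (-0.22, 0.398), where H2-Ob fell by 1.79, MHC class I (-0.23, 0.418), where its activator Nlrc5 fell by 0.94, complement (-0.17, 0.344), with Cfp (-0.57) and Cfb (-0.75), dendritic cells (-0.43, 0.185), eosinophils and mast cells (-0.69, 0.339), with Hdc (-0.69), and Toll-like receptor and NF-kB signalling (-0.09, 0.617), with Relb (-0.40) and Tnfaip3 (-0.35); the first number is the median and the next the fry adjusted p. In the immediate early and heat shock list (median -0.59, fry adjusted p = 0.211) Junb fell by 0.94 and Nr4a1 by 1.36. With library totals the classically activated, monocyte, dendritic and type I interferon lists passed as lower (fry adjusted p = 0.0316, 0.0444, 0.0444 and 0.0398). Ccl12 did not pass with library totals (limma adjusted p = 0.0608) or voom quality weights (0.0559), nor did Nr4a1, Cxcl1 and Csf3r with a robust variance fit (0.0911, 0.0515 and 0.0538). Among these genes Ly6c2 lost its call without any 1 library except PBS replicate 1 and VEGF-C replicate 2 (limma adjusted p up to 0.102), Csf3r without any 1 library except PBS replicate 1, 2 and 4 (0.0839), Cxcl1 without PBS replicate 2 or VEGF-C replicate 1, 2 or 3 (0.0597), Ccl12 without any 1 library except PBS replicate 1 and 4 (0.0751), Cfp without PBS replicate 3 or 4 or VEGF-C replicate 3 or 4 (0.0634), Cfb without any 1 library except PBS replicate 1 and VEGF-C replicate 2 (0.111), Hdc without any 1 library except VEGF-C replicate 2 (0.104), Relb without any 1 library except PBS replicate 4 and VEGF-C replicate 1 (0.0944), Tnfaip3 without any 1 library except PBS replicate 2 and 4 and VEGF-C replicate 4 (0.0863), and Nr4a1 without PBS replicate 3 or VEGF-C replicate 1, 3 or 4 (0.0854).

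The lists of oxidative phosphorylation, glycolysis and the contractile apparatus passed fry as higher, and only that of glycolysis was above coding genes of like abundance, which were themselves higher at these levels. All 24 nuclear-encoded oxidative phosphorylation genes had positive fold changes (median 0.29); 6 passed over all genes and 14 adjusted over the list alone, among them the cytochrome oxidase subunits Cox5a (0.45 ± 0.08) and Cox4i1 (0.39 ± 0.10) and the complex I subunits Ndufa8 (0.45 ± 0.09) and Ndufb5 (0.30 ± 0.08). All 14 glycolysis and hypoxia genes had positive fold changes (median 0.41); 6 passed over all genes and 8 adjusted over the list alone, among them the mitophagy receptor Bnip3 (0.54 ± 0.09), Pdk1 (0.45 ± 0.11), Pgk1 (0.42 ± 0.09) and Ldha (0.38 ± 0.09). In the cardiomyocyte contractile list (median 0.34) 14 of 15 fold changes were positive; the sarcomere protein gene Actn2 (0.61 ± 0.12) and the calcium-binding Casq2 (0.47 ± 0.13) passed, while Ttn (0.50 ± 0.16), Actc1 (0.48 ± 0.16) and Myh6 (0.34 ± 0.28) did not; adjusted over the list alone 4 passed. Ttn and Actc1 did pass with limma-voom (adjusted p = 0.0404 and 0.0339), its quality weights, a robust variance fit and the authors' adjusted p-value. Neither passed under another scaling. The lists passed fry with adjusted p = 0.0331, 0.0319 and 0.0469 in this order (adjusted p = 0.724 with an estimated correlation for each). Random coding lists matched on mean value, a comparison added after the data were seen, had 95% of medians between 0.14 and 0.32 for oxidative phosphorylation, between 0.05 and 0.30 for glycolysis and between 0.12 and 0.36 for the contractile list. With upper-quartile factors the fry adjusted p was 0.0594, 0.0554 and 0.0946, and with library totals 0.238, 0.0933 and 0.238; that of the contractile list was 0.0501 with TMM factors and 0.0525 with the residual component. The oxidative phosphorylation call was kept only without PBS replicate 3 or 4, the contractile call only without PBS replicate 4, and the glycolysis call without PBS replicate 1 or 4 or VEGF-C replicate 4; the highest fry adjusted p among these fits was 0.112, 0.122 and 0.112. Mitochondrially encoded genes (median 0.47, fry adjusted p = 0.282) and fatty acid oxidation (0.19, 0.398) did not pass, though the coactivator Ppargc1a (1.01 ± 0.17) and the dehydrogenase Acadl (0.41 ± 0.10) did. Adjusted over the fatty acid oxidation list alone, 4 members were higher and 2 lower. The mitochondrially encoded median lay above the range of matched coding lists (0.07 to 0.34), and that of fatty acid oxidation lay within its range (0.05 to 0.28). The cardiac stress list (0.30, 0.339) did not pass either, with Nppb at 0.47 ± 0.17 and Myh7 at 0.33 ± 0.15. With library totals Cox4i1, Ndufa8, Ndufb5, Pdk1, Pgk1, Ldha, Casq2 and Acadl did not pass (limma adjusted p from 0.0532 to 0.345). Cox4i1, Ndufb5, Ldha and Casq2 did not pass with upper-quartile factors either (limma adjusted p = 0.0604, 0.0645, 0.0541 and 0.0662), nor did Casq2 with voom quality weights (0.0509). Among these genes Cox4i1 lost its call without PBS replicate 1 or 2 or VEGF-C replicate 1 or 2 (limma adjusted p up to 0.0780), Ndufb5 without PBS replicate 2 or 4 or VEGF-C replicate 1 or 2 (0.0649), Pdk1 without PBS replicate 2 or VEGF-C replicate 3 or 4 (0.0578), Ldha without PBS replicate 2 or VEGF-C replicate 1, 2 or 3 (0.0705), Casq2 without any 1 library except PBS replicate 4 and VEGF-C replicate 1 (0.0920), and Acadl without VEGF-C replicate 2, 3 or 4 (0.0575).

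Of 14 lymphatic marker genes 2 passed, the receptor Flt4 and the integrin Itga9, both higher. The transcript of the administered factor, Vegfc, had a fold change of 0.05 ± 0.21, and the lymphatic endothelial genes Prox1 (0.01 ± 0.10), Lyve1 (0.11 ± 0.35) and Pdpn (0.05 ± 0.16) did not pass, each with the sign changed under library totals. Flt4 rose by 0.40 ± 0.12 (limma adjusted p = 0.0482), and this call was lost under each other scaling (adjusted p from 0.0511 to 0.267), with limma-voom (0.0519), with its quality weights (0.0513) and without any 1 library except PBS replicate 3 and VEGF-C replicate 4 (limma adjusted p up to 0.118). Itga9 rose by 0.32 ± 0.08 and lost its call with library totals (0.231) and without VEGF-C replicate 3 (0.0632). The lymphatic endothelium list had a median of 0.16 (fry adjusted p = 0.414). Of the VEGF and angiopoietin list (median 0.17, fry adjusted p = 0.0870), Vegfb (0.65 ± 0.12), Flt1 (0.36 ± 0.10) and Flt4 passed. In the blood vessel endothelium list (0.14, 0.772), Vwf rose by 0.64 and Egfl7 fell by 0.92. The directions of the VEGF and blood vessel lists changed with library totals, and that of the blood vessel list with upper-quartile factors. Flt1 lost its call with upper-quartile factors (limma adjusted p = 0.0759) and library totals (0.263), and Vwf with library totals (0.0552). The call of Flt1 was also lost without any 1 library except PBS replicate 1 and VEGF-C replicate 2 (limma adjusted p up to 0.102).

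**Figure D3:**
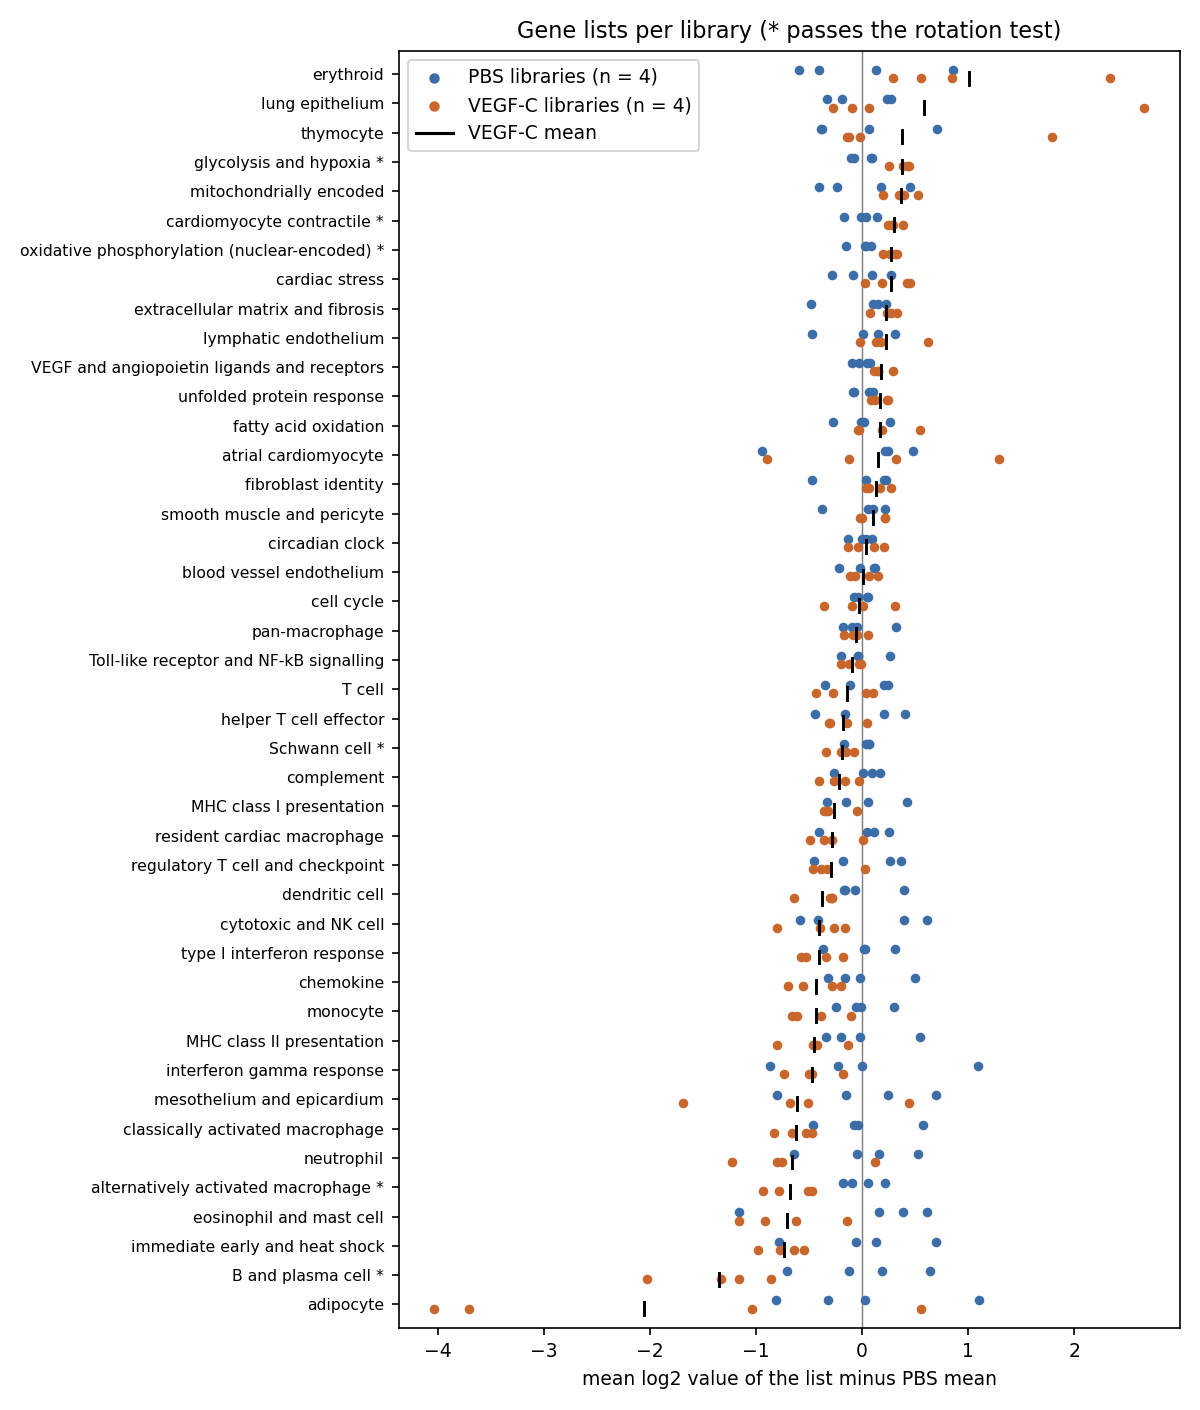
Mean log2 value of each of the 43 gene lists per library, minus the PBS mean of that list (blue PBS, orange VEGF-C, black bar the VEGF-C mean, n = 4 per group); an asterisk marks the 6 lists that passed fry. In the alternatively activated macrophage list all 4 VEGF-C libraries lie below all 4 PBS libraries, and 2 VEGF-C libraries lie far below the rest in the adipocyte list.

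In the matrix and fibrosis list 3 of 21 genes passed, all higher, among them collagen Col1a1 (0.69 ± 0.14) and Tgfb1 (0.54 ± 0.09); the list did not pass (median 0.25, fry adjusted p = 0.305). The fibroblast identity list (0.17, 0.687), the smooth muscle and pericyte list (0.14, 0.700) and the cell cycle list (-0.02, 0.973) had 0 members past the threshold. In the unfolded protein response list (median 0.14, fry adjusted p = 0.0870) Herpud1 (0.62) and Dnajb9 (0.39) rose, and in the circadian clock list (0.00, 0.455) Per2 (0.72) and Cry1 (0.65) rose. With library totals the fibroblast, smooth muscle, unfolded protein response and clock lists changed direction. The Schwann cell list passed fry as lower (median -0.25, adjusted p = 0.0331; adjusted p = 0.724 with an estimated correlation), and the call was lost with the residual component (0.0741), with camera at a preset correlation (0.349) and without any 1 library except PBS replicate 3 (adjusted p up to 0.184). Its median lay within the range of matched coding lists (-0.49 to 0.15). Its members parted: the myelin gene Mbp (-0.55 ± 0.13) fell, Sox10 (-0.30 ± 0.28) did not pass, and Pmp22 had a positive fold change (0.40 ± 0.13) that did not pass over all genes; adjusted over the list alone 1 was higher and 2 lower. The call of Dnajb9 was lost with upper-quartile factors (limma adjusted p = 0.0561), with library totals (0.234) and without any 1 library except PBS replicate 1 and VEGF-C replicate 2 (limma adjusted p up to 0.0980).

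Markers of other tissues varied between single libraries. The adipocyte list averaged 5.24 and 5.57 (log2) in VEGF-C replicates 2 and 4, against 8.23 and 9.82 in the other VEGF-C libraries and 8.46 to 10.37 in PBS (fry adjusted p = 0.339). The erythroid list was 13.96 in VEGF-C replicate 2, against 11.92 to 12.48 in the other VEGF-C libraries (fry adjusted p = 0.319). The thymocyte list was 6.42 in VEGF-C replicate 3, the lung epithelium list 6.74 in VEGF-C replicate 1, and the mesothelium list ranged from 8.41 to 10.54 in VEGF-C and from 9.29 to 10.80 in PBS (fry adjusted p = 0.619, 0.774 and 0.451). The atrial cardiomyocyte list had a median of 0.09 (fry adjusted p = 0.892), and its direction changed with library totals.

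By annotation class, examined after the values were seen, 274 of 1350 long noncoding genes were lower and 9 higher, with a median log2 fold change of -0.38. Among 14579 protein-coding genes 1176 were lower and 1249 higher. The coding genes with the fewest reads had a median of -0.38 and those with the most 0.24, so each class was set beside coding genes matched on mean value. Matched coding genes had a median of -0.28 (95% of draws from -0.31 to -0.24) for the long noncoding genes. The 28 small RNA genes had a median of -0.87, against -0.38 (-0.68 to -0.14) for matched coding genes, and 174 immunoglobulin V segments, of which 9 were lower and 0 higher, had a median below the range of matched coding genes (-0.35 to -0.18). Processed pseudogenes lay the other way, at 0.03 against -0.19. Reads assigned to Rn18s-rs5, a ribosomal RNA gene chosen after its values were seen, made up 0.509% ± 0.274 of reads in PBS and 0.129% ± 0.0616 in VEGF-C (SD, n = 4). The call of Rn18s-rs5 was lost without VEGF-C replicate 1 (limma adjusted p = 0.0512).

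**Figure D4:**
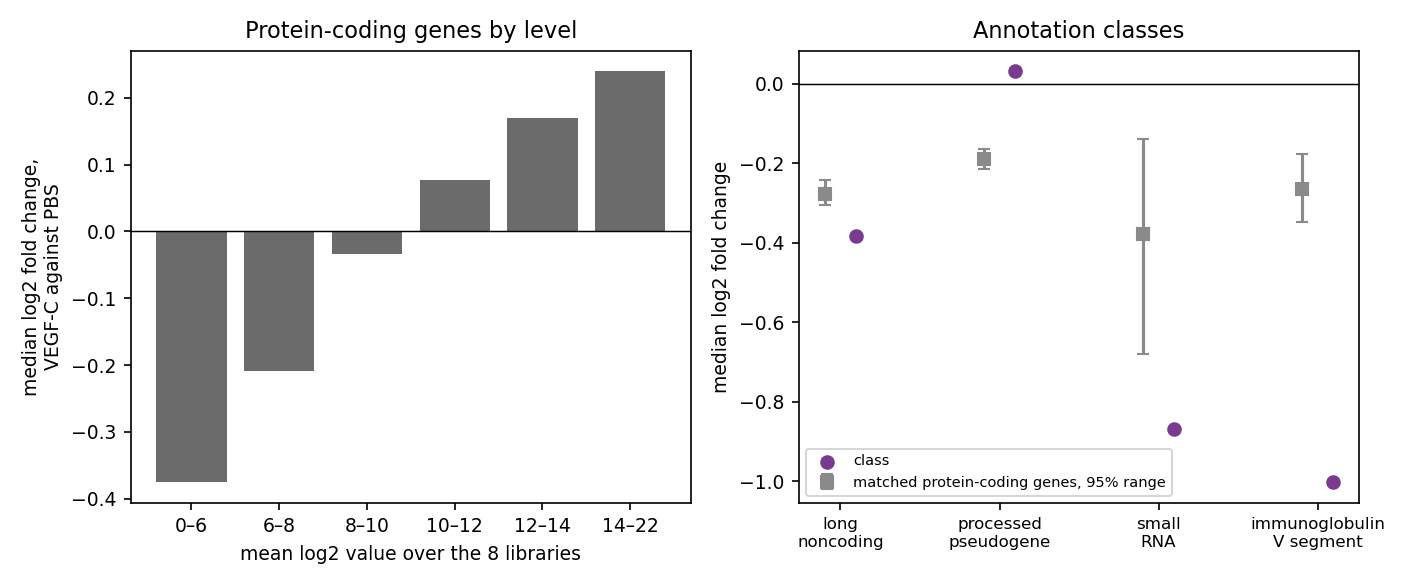
Median log2 fold change, VEGF-C against PBS: bars show protein-coding genes in 6 ranges of mean log2 value, from -0.38 to 0.24; purple points show 4 annotation classes beside the median (grey squares) and 95% range (bars) of protein-coding genes matched on mean value. Long noncoding genes lie at -0.38, below their matched range of -0.31 to -0.24.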

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

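Among 328 groups of 4 libraries examined (the named genes, list means and read totals, once per group), 20 had a library far from the other 3; chance alone sets apart about 1 in 20 groups, or 16.4 here. Each value below is the gap from that library to the nearest other, divided by the range of the group.

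In VEGF-C replicate 1, Shfl was low (0.979), and Tnf (0.956), Rin3 (0.891), the MHC class I list (0.862) and the lung epithelium list (0.882) were high. In VEGF-C replicate 2, Cd68 (0.890) and the dendritic cell list (0.935) were low, and Oasl2 (0.927) and the immunoglobulin kappa constant gene Igkc (0.968) were high. In VEGF-C replicate 3, the thymocyte list (0.935) and Ucp1 (0.893), the uncoupling protein of brown fat, were high. In VEGF-C replicate 4, Pgk1 (0.896) and Cox5a (0.891) were low, though Cox5a lay within 14.38 to 14.42 in this group and above every PBS library.

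In PBS replicate 1, Hdc (0.863) and Ucp1 (0.900) were high and Pmp22 (0.844) was low. Ucp1 stood at 10.11 on the log2 scale in that library, against 4.15 to 4.74 in the other PBS libraries. In PBS replicate 2, Klf9 was low (0.877). In PBS replicate 3, Actn2 (0.888) and the Schwann cell list (0.857) were low. In PBS replicate 4, Ccl12 was high (0.914), at 9.43 against 8.56 to 8.63. Igkc, Ucp1 and Klf9 were chosen after their values were seen.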

How the results depend on the processing

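Of the 99 genes that were chosen for naming and passed, 0 changed sign under any setting; 28 lost the call when 1 library was left out and 21 under another setting. The 6 lists that passed kept their direction under every setting, and all 6 passed with limma-voom on the recovered reads. No paired analysis was possible because the animal numbers in the labels do not repeat between groups and the columns' own numbers tie to no animal. Median-of-ratios factors and no further filter are what the deposited values already use. The edgeR and DESeq2 tests, the robust edgeR fit and the surrogate variable were not run. Settings chosen after the data were seen were TMM factors, robust eBayes, a pseudocount of 1, protein-coding genes only, the residual component, thinned reads, the authors' adjusted p and matched coding lists. Those that count genes gave between 2554 and 4075, and those that test lists with fry gave 4 to 8.

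The count of changed genes (2949) was 4694 at an adjusted p of 0.1 (2276 higher) and 635 with a log2 fold change of at least 1 (23 higher, 612 lower), as fewer or more genes meet those thresholds. The number higher (1328) was 769 with upper-quartile factors and 243 with library totals, and the number lower (1621) was 3572 with library totals, whose shift of all genes was -0.19. Leaving out 1 library gave 1684 to 2906 genes, 591 to 1268 higher and 1093 to 1638 lower, with 3 animals in 1 group.

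The count of lists (6) was 22 against matched coding lists, a test that takes genes as independent and lost the oxidative phosphorylation (0.335), contractile (0.189) and Schwann cell (0.641) calls. It was 2 with upper-quartile factors, 17 with camera at a preset correlation and 0 with an estimated correlation, and the cause was not tested. Camera compares a list with other genes, which fry does not do. With an estimated correlation 0.724 was the lowest adjusted p of any list. The lymphatic endothelium list, with a fry adjusted p of 0.414, shared it, so this value does not tell the called lists from others. The count of lists was also 0 with the exact permutation, where no adjusted p was under 0.154. The smallest p which that permutation can give is 0.0286. Adjustment over all lists keeps this value above 0.05 unless most lists reach it. A count of 0 there was thus nearly fixed by the design and says little about the calls. Leaving out 1 library gave 0 to 5 lists: 0 without PBS replicate 2 or VEGF-C replicate 1, 2 or 3, 1 without VEGF-C replicate 4, 2 without PBS replicate 1 or 3, and 5 without PBS replicate 4. With 200 changed genes among 18835, the simulated test recovered 24% of genes changed by 0.5 on the log2 scale, so small changes can be missed. In the data 2949 genes passed, which makes the adjusted threshold less strict, so that share is not the share recovered here.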

Other observations

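The tests of small RNA genes, of activation against general macrophage genes and of the clock genes, and the permutation of the glucocorticoid genes, were chosen after the values they use were seen, as were the genes named in this part outside the rule. Splits of the 8 libraries into 4 and 4 were used to ask whether grouping by chance could give the counts: the real grouping gave 2949 genes and the highest of the other splits 25, so that 1 of 35 splits, the real one, reached that count. For lists, the real grouping gave 6 and the highest other split 4, and again 1 of 35 splits reached it. A share of 1 in 35 is the smallest these splits can give. Every other split mixes treated and control animals, so any difference between the treatments adds to the spread within its groups. The splits thus show that the real grouping gave the highest count of genes and of lists, but they do not exclude chance. For lists the margin was small, 6 against 4.

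Further single genes, picked for small p-values, were lower in 4 of 4 VEGF-C libraries than in any PBS library; no list of splicing genes was tested, and the Toll-like receptor and NF-kB list did not pass (median -0.09, fry adjusted p = 0.617). They were Pnisr (-1.43 ± 0.10), Leng8 (-1.38 ± 0.11), the splicing factor Srsf5 (-1.37 ± 0.13), Ccnl2 (-1.25 ± 0.09) and Rsrp1 (-1.12 ± 0.10). Others were the inhibitory receptor Lilrb4a (-2.10 ± 0.22), the adaptor Card9 (-1.48 ± 0.14), the growth factor receptor chain Csf2ra (-1.23 ± 0.10), the pore-forming Gsdmd (-1.23 ± 0.11), the kinase Ikbke (-1.21 ± 0.10) and the kinase Jak3 (-0.94 ± 0.08). The nuclear RNAs Malat1 (-0.89 ± 0.18), Kcnq1ot1 (-0.98 ± 0.21) and Airn (-1.15 ± 0.14) were lower as well.

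Long noncoding RNAs were lower in VEGF-C than coding genes of like abundance. A difference in sequencing depth argues poorly for this: after all libraries were thinned to 1 normalized depth, the gap to matched coding genes kept 0.978 of its size. A contribution of genomic DNA to the PBS libraries cannot be told apart, since the excess of PBS reads per exon kb was 2.62 times larger in the 450 most abundant than in the 450 least abundant long noncoding genes (bootstrap interval 2.05 to 3.34), where DNA would give about equal values and a ratio above 3 was needed to set it aside. Less nuclear or unspliced RNA in the VEGF-C libraries cannot be told apart either. Of 28 small RNA genes 26 were lower, but so were 17 to 26 genes in 95% of coding lists matched on mean value. The median of the small RNA genes, -0.87, did lie below the range of matched coding genes (-0.68 to -0.14). The class was chosen after its values were seen, so neither value decides. An effect of the treatment on these RNAs stays open and was not tested.

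All 24 genes of the 2 macrophage activation lists had negative fold changes, of which 6 passed; the alternatively activated list passed fry (adjusted p = 0.0319; adjusted p = 0.724 with an estimated correlation) and the classically activated list did not (fry adjusted p = 0.0870). The trend of low-abundance transcripts to be lower is argued against as the whole cause: the median of the 24 activation genes, -0.55, lay at percentile 0 of 10000 random coding lists matched on mean value (95% between -0.24 and 0.08). Fewer macrophages in the tissue cannot be told apart: the activation genes fell by 0.59 more than the pan-macrophage genes (log2, exact permutation p = 0.0286), but with the level of coding genes of like abundance taken off every gene the gap was 0.37 (exact permutation p = 0.143). Lower activation of the macrophages stays open beside it, and whether the treatment or the severity of the disease differed was not tested. The values are of whole heart tissue, so which cells these transcripts came from was not tested either. The neutrophil (median -0.63), dendritic cell (-0.43) and monocyte (-0.39) lists also had negative medians, without passing fry.

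Zbtb16, and, seen afterwards, Fkbp5 (1.26 ± 0.21), Tsc22d3 (0.95 ± 0.18) and Klf9 (0.45 ± 0.09; limma adjusted p = 0.0720 with library totals), were higher in VEGF-C, and all 4 are known to be induced by glucocorticoids. Ddit4, looked at with them, did not pass (1.00 ± 0.31, limma adjusted p = 0.0560), nor did the clock gene Per1 (0.03 ± 0.14, limma adjusted p = 0.905). Higher glucocorticoid signalling in the VEGF-C animals is a candidate explanation. Among 12 other glucocorticoid-induced genes not inspected before, 5 passed, all higher, and the median was 0.41. For these 12 genes fry gave an unadjusted p = 0.00284, and an exact permutation of their mean gave p = 0.0286, the smallest it can give. Mfsd2a (-0.78 ± 0.47) and Arrdc2 (-0.10 ± 0.09) were negative. Neither test compared these genes with coding genes of like abundance, and the coding genes with the most reads had a median of 0.24. How much of the rise that trend explains was not tested. Another time of day at tissue collection cannot be told apart: the late clock genes Per2 and Cry1 rose by 0.78 against the early ones, but they were picked because they rose, so this decides nothing, and the 8 early genes did not differ detectably (0 passed, mean difference -0.09, exact permutation p = 0.686). No label gives the hour of collection, and a direct effect of the growth factor was not tested.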
